A study of Oryza sativa with 6 samples.

How the data were processed

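Roots of 6-day-old rice seedlings of cultivar TN-67 were profiled on 6 dual-colour Agilent arrays, 3 for a short and 3 for a long exposure to hexavalent chromium, Cr(VI), at 50 µM. Per the labels, the short samples pooled roots collected after 1 h and 3 h, the long samples came from 24 h, and the RNA of the treated roots carried Cy5 while the RNA of roots in water carried Cy3 on every array. No dye was swapped. Amplification and labelling followed a linear amplification kit, per the labels' protocols. The labels call the samples biological replicates and do not say whether control RNA was shared between arrays.

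The spot intensity values were written by Agilent Feature Extraction 10.7.1.1, per the file headers, as the median pixel brightness of each spot and of its local background on a linear scale. The files also hold log10 ratios of Cy5 over Cy3 and processed signals, already background-subtracted and dye-normalized, per the file headers. The deposited table of the whole series holds log2 ratios for 42475 probes, which matched the log2 of processed red over processed green, so that scale and direction were settled, and the column medians ran from -0.178 to 0.0385, so no centring on the median had been done. The log10 ratios deposited in the scanner files were set to 0 for spots without a usable signal and were not used.

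From the median intensities, the background was corrected with normexp (offset 50) and each array was normalized by loess in limma 3.58.1 under R 4.3.3, with control spots and outlier spots at weight 0. No mean signal columns were in the files, so medians took their place. Outlier spots (163 to 1936 per array of 43734) were left out and spots of one probe were averaged. Of several probes of a locus the one with the highest mean brightness over all arrays was kept. A gene was tested when its signal was well above background in either channel on at least 3 of the 6 arrays and at least 2 values remained per exposure. That left 23464 of 30218 genes, of which 23188 were loci, 265 were microRNA probes and 11 were other probes. The offset pulls ratios of dim genes toward 0. Per array, 68.14% to 82.53% of the spots were well above background in green and 73.05% to 80.26% in red, and no spot was saturated. The number of arrays limits the precision.

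One limma model (lmFit, eBayes) over the 6 arrays gave the short and the long mean log2 ratio against 0 and their difference, with 4 residual degrees of freedom, 4.36 prior degrees of freedom and Benjamini-Hochberg adjustment over all genes tested. Calls needed an adjusted p under 0.05, and 2-fold calls besides an absolute log2 ratio of at least 1. The control channel was compared between the exposures with limma on log2 Cy3 values after the same background correction and quantile normalization. A channel that was not well above background on any array of a group gives only a bound on the fold, computed from the channel values after loess and Aquantile normalization. Such a bound is open to dye bias.

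The files do not pair the loci with gene names. None of the 29689 locus numbers and none of the 40822 sequence accessions in the probe names matched the reference table of gene symbols, so 0 of the 36 gene lists fixed before the data were examined could be filled and loci stay unnamed. The fixed rule for named genes took the genes with the largest changes in each direction among those with adjusted p under 0.05, the same sign on all 3 arrays (for the difference, no overlap of the exposures) and a signal well above background in either channel on every array of the comparison. Its demand for an informative description could not be applied, and only the first 2 loci in each direction are given per comparison. The 510 microRNA probes carry names in the files. They are grouped by family number, and those that changed at least 2-fold are named. The miR398b pair and the probes with the largest change of the miR168 family after the short exposure and of the miR156 family at 24 h are named too, although they stayed under 2-fold. All these choices were made after the data were seen. The tags 5'seq, 3'seq and Mature are printed as the files give them, without a statement of which transcript, precursor or mature, was read. Families with at least 5 tested probes, and all microRNA probes together, were tested with camera at a preset inter-gene correlation of 0.01, with the estimated correlation and fry beside it. Chromosomes are those written in the locus and probe names. No genome build was used.

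The short arrays lay on slides 1 and 2 and the long arrays on slide 3, so no slide held both exposures. The slide was therefore added only as a random block. Other background corrections, normalizations, filters, probe rules, variance priors, array weights, the replicate number as a block and the omission of each array were run as alternatives fixed before the data were examined.

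The pipeline was tested on simulated arrays with 200 changed loci, of which 97 with a true change of 0.5 and 96 with a change of 1 were among the 23455 genes tested. Of the loci changed by a log2 ratio of 1, 100% were called for the short and for the long comparison, with median estimates of 0.893 and 0.908; of those changed by 0.5, 93.9% and 95.8% were called. For the difference between exposures, 100% of the loci with a true difference of 1 and 56.7% of those with 0.5 were called. To show what control RNA shared between the exposures would give, 20 draws of unchanged genes with the measured spread were put through the same fit. The control channel test called 99.5% of 191 loci changed by 1 and 47 of 23264 unchanged genes. The shares of simulated loci called, in the ratios and in the control channel, were not split by brightness or by spread. They therefore give no recovery for dim genes or for genes as variable as Os11g0592200 (SD 2.34 at 24 h).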

Results

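Gene expression in rice roots under Cr(VI), a toxic oxidizing form of chromium, was measured as the log2 ratio of treated over control signal on 6 arrays, 3 per exposure. The series asked how the transcript profile after a short exposure, pooled from 1 h and 3 h, compared with that after 24 h. Across genes, the ratios correlated at 0.881 to 0.923 between the short arrays, at 0.915 to 0.960 between the long arrays and at 0.527 to 0.631 between exposures. Genes are not independent replicates. The median signal of the arrays lay between 328 and 535.5 in the control channel and between 263 and 438.5 in the treated channel, against local backgrounds of 36 to 73.5 and 57 to 62.

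After the short exposure, the loci that changed at least 2-fold mostly rose: 1079 genes were higher and 150 were lower. The locus Os04g0203600 on chromosome 4 rose by a log2 ratio of 5.17 ± 0.28 (SD, n = 3), and its control signal was not well above background on any short array, so that the treated signal was at least 36.1-fold higher (limma adjusted p = 9e-08). Os06g0142400 on chromosome 6 rose by 5.13 ± 1.51 (SD, n = 3, adjusted p = 0.00037), with values of 3.5, 5.4 and 6.48 on the 3 arrays. Os02g0667500 on chromosome 2 fell by 2.51 on the log2 scale (SD 0.243, n = 3, adjusted p = 4.2e-06), and the second probe of this locus gave -2.50. Os10g0167900 on chromosome 10 fell by 2.25 (SD 0.598, n = 3, adjusted p = 6.6e-05).

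Of 265 microRNA probes tested, 84 were higher and 21 were lower, and 1 in each direction reached 2-fold. For comparison, 7172 of all 23464 genes tested were higher and 5665 were lower. The miR416 3'seq probe rose by 1.19 ± 0.20 (SD, n = 3, adjusted p = 8.8e-06), and the miR171g 3'seq probe fell by 1.09 (SD 0.909, n = 3, adjusted p = 0.015), with values from -2.01 to -0.20. The miR171g value was -0.62 without short replicate 1 (adjusted p = 0.086), -1.11 without short replicate 3 (adjusted p = 0.051) and -2.01 without the short arrays on slide 2 (adjusted p = 0.0037), so that the call was lost in the former pair. Of the miR171 family, which targets GRAS transcription factors of root and shoot meristems, 7 of 19 probes fell and 1 rose. Of the miR395 family, which is induced by low sulfate and targets ATP sulfurylase and a sulfate transporter, 11 of 29 probes rose and none fell, with a median of 0.11 (camera adjusted p = 0.142). That count was 5 without short replicate 1, 7 without short replicate 3, 6 with Agilent's processed signals, 5 with median centring and 5 without the short arrays on slide 2. All 5 tested probes of miR168, which targets the ARGONAUTE protein that carries microRNAs, rose, with a median of 0.33, led by the miR168a 3'seq probe at 0.64 ± 0.03 (SD, n = 3; 0.33 with Agilent's processed signals and 1.25 with median centring), and 2 passed without the short arrays on slide 2. Among 15 sets tested with camera, miR168 and miR171 had the smallest p, and both missed the threshold (adjusted p = 0.091 for each, and adjusted p = 0.825 with an estimated correlation).

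Over all genes tested with limma, 12837 of 23464 passed for the short exposure, 7172 of them higher and 5665 lower. With Agilent's processed signals the split turned to 5705 higher and 7679 lower, and the 2-fold calls became 1850 higher and 734 lower. All arrays had the same dye orientation, so a bias of a probe for one dye adds to each ratio against control.

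**Figure D1:**
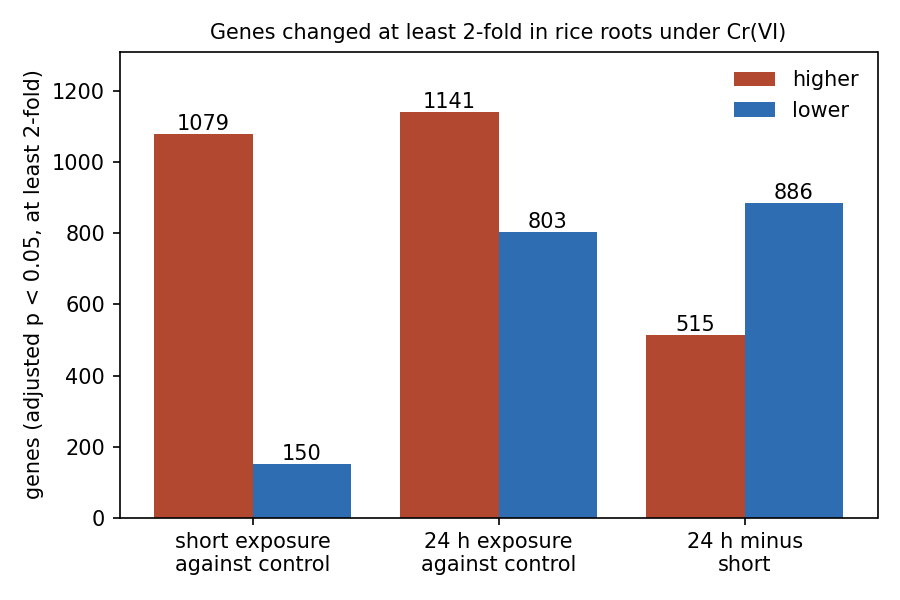
Number of genes (vertical axis) with a limma adjusted p under 0.05 and at least a 2-fold change, for the short exposure against control, 24 h against control and 24 h minus short (bars in pairs, higher and lower). The short exposure had 1079 higher and 150 lower genes, and 24 h had 1141 and 803.

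After 24 h, 1141 genes were at least 2-fold higher and 803 at least 2-fold lower. The loci Os10g0527400 and Os10g0525600, both on chromosome 10, rose by log2 ratios of 6.20 ± 0.09 and 5.81 ± 0.10 (SD, n = 3 each), and had already risen by 4.94 ± 0.07 and 4.55 ± 0.16 after the short exposure. Os01g0550800 on chromosome 1 fell by 5.69 on the log2 scale (SD 0.900, n = 3, adjusted p = 8.9e-07). Os09g0491100 on chromosome 9 fell by 4.72 (SD 0.765, n = 3, adjusted p = 7.7e-07), and the other probes of this locus gave -4.67 to -4.77.

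At 24 h, 76 of the 265 microRNA probes were higher and 38 lower, 10 and 5 of them by at least 2-fold. For comparison, 7895 of all 23464 genes tested were higher and 7256 were lower. The miR528 3'seq probe rose by 3.23 ± 0.07 and its 5'seq probe by 1.39 ± 0.11 (SD, n = 3 each; adjusted p = 7.8e-09 and 4.4e-07), the 3'seq probe by 5.09 with Agilent's processed signals. The Mature probe of this locus was at 0.09 ± 0.06 (adjusted p = 0.35). The 3'seq probe was well above background in the control channel on 2 of the 3 arrays. Probes of miR408, a copper-regulated microRNA that targets plantacyanin and laccase transcripts, rose by 1.45 ± 0.39 (5'seq) and 1.05 ± 0.28 (Mature, 2.25 with Agilent's processed signals). The miR408 3'seq probe was at 0.985 ± 0.17 and had already risen by 0.419 ± 0.03 after the short exposure (limma adjusted p = 0.0014). Of miR398, which targets copper/zinc superoxide dismutase transcripts in other plants, the miR398b 3'seq probe was higher by 0.66 ± 0.16 and the 5'seq probe by 0.58 ± 0.18. Both had already risen after the short exposure, by 0.55 ± 0.09 and 0.31 ± 0.06, and neither difference passed (adjusted p = 0.44 and 0.067); the short 5'seq call was lost with Agilent's processed signals (adjusted p = 0.055) and without the short arrays on slide 2 (adjusted p = 0.22). Of miR399, which is induced by low phosphate, 7 of 13 probes rose and none fell, led by miR399i Mature at 2.87 ± 0.58 and miR399b 3'seq at 2.79 ± 0.75 (camera adjusted p = 0.22 for the family). The miR160e 3'seq probe, of a family that targets auxin response factors, rose by 1.74 ± 0.31, while the 5'seq probe of this locus was lower, at -0.34 ± 0.23 (adjusted p = 0.0064), and its Mature probe was at 0.01 ± 0.13. Of the 11 miR160 probes, 3 rose and 3 fell. Smaller rises were measured for miR416 3'seq (1.26 ± 0.08), miR414 5'seq (1.08 ± 0.06) and miR531 5'seq (1.03 ± 0.28), which had been at 1.19, 0.85 and 0.46 after the short exposure. The miR416 5'seq, miR414 3'seq and miR414 Mature probes did not pass at 24 h (adjusted p = 0.17, 0.056 and 0.54).

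The microRNA probes that fell at least 2-fold at 24 h were all of the miR171 family. The miR171h 5'seq and 3'seq probes fell by 1.91 and by 1.34 on the log2 scale (SD 0.163 and 0.124, n = 3 each). They were at -3.02 and -3.56 with Agilent's processed signals. The treated channel of the 3'seq probe was well above background on only 1 of the 3 long arrays, so the size of its fall is uncertain. The Mature probe of this locus was at -0.34 ± 0.29 (adjusted p = 0.055). The miR171g 3'seq probe was at -1.82 ± 0.51, and the miR171f 5'seq and 3'seq probes were at -1.11 ± 0.36 and -1.04 ± 0.40. In all, 11 of the 19 miR171 probes fell and 1 rose, and 7 fell and 1 rose without long replicate 1. Camera did not call the family (adjusted p = 0.084, and adjusted p = 0.864 with an estimated correlation), while fry, which asks only whether the probes moved one way on balance, gave adjusted p = 0.00441. Fry did not set miR171 apart. Its adjusted p at 24 h was smaller for miR168 (0.000661), miR156 and miR399 (0.000954 each), and was 0.0276 for all microRNA probes together. It did not pass for miR395 (fry adjusted p = 0.124), among others. Of miR156, which targets SPL transcription factors, 10 of 22 probes rose and 1 fell, led by the miR156d 3'seq probe at 0.87 ± 0.12, which had been at 0.75 ± 0.07 after the short exposure (camera adjusted p = 0.183 for the family at 24 h).

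**Figure D2:**
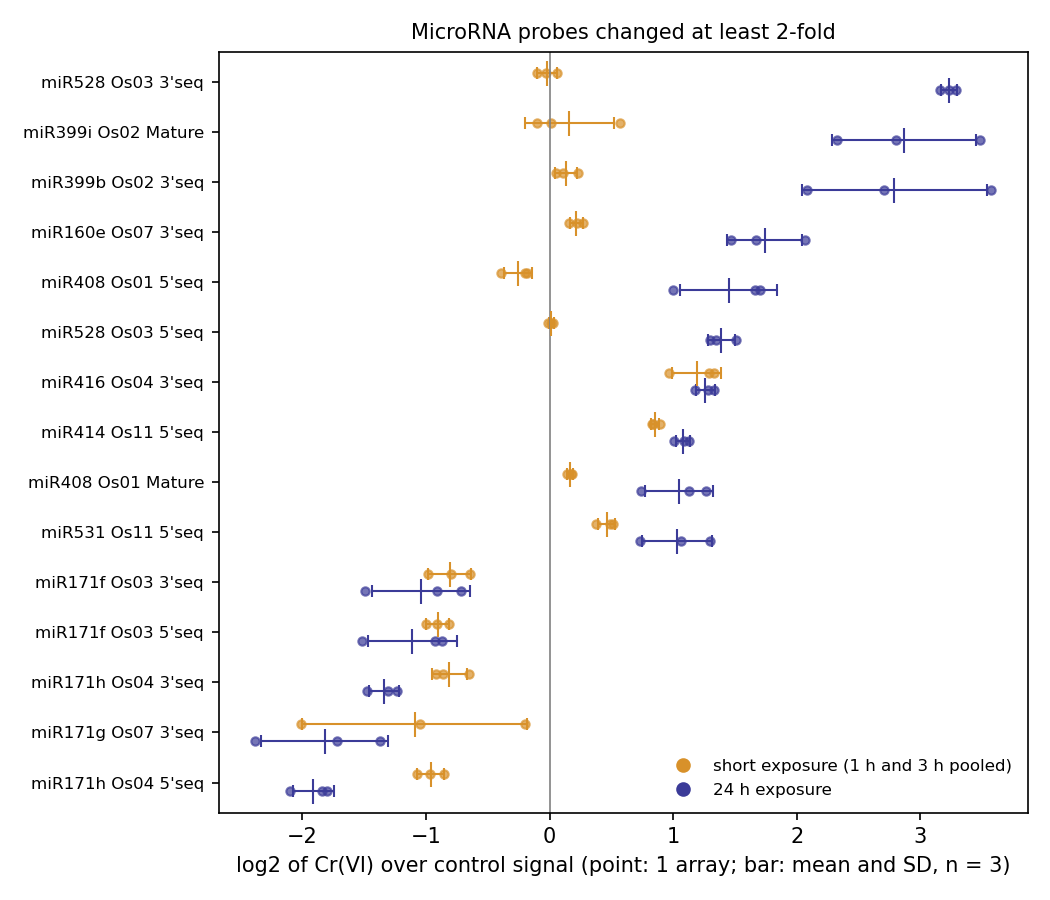
Log2 ratio of treated over control signal (horizontal axis) for the 15 microRNA probes that changed at least 2-fold in any comparison; each point is 1 array, and bars give the mean and SD of 3 arrays per exposure. The miR171 probes lie below 0 at both exposures, while the plotted miR528, miR399 and miR408 probes are near 0 after the short exposure and above it at 24 h, the miR528 3'seq probe being not well above background in either channel on the short arrays.

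Over all genes, 15151 passed at 24 h, 7895 higher and 7256 lower. Median centring in place of loess lowered the median ratio at 24 h by a shift of -0.102 and gave 5171 higher and 8551 lower, and 972 higher and 1321 lower at 2-fold. With Agilent's processed signals the 2-fold calls became 1865 higher and 1733 lower.

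The series' central comparison set 24 h against the short exposure. Of the genes tested, 515 were at least 2-fold higher and 886 at least 2-fold lower at 24 h than after the short exposure. The treated signal of Os09g0483200 on chromosome 9 was at least 2.93-fold higher than control after the short exposure, where the control signal was not well above background on any array, and the log2 ratio was 5.42 ± 0.26 (SD, n = 3) at 24 h, where the control was well above background on 1 of 3 arrays. Its difference passed the test (adjusted p = 3.5e-06), but with the short ratio only a bound its size is not fixed. Os11g0592200 on chromosome 11 went from 0.19 ± 0.32 to a mean of 4 with an SD of 2.34, with long values of 5.56, 5.14 and 1.31, and its difference of 3.81 (adjusted p = 0.013) was lost without long replicate 2 (adjusted p = 0.055). Os09g0409100 on chromosome 9 was at 0.87 ± 0.46 after the short exposure and at -4.31 ± 0.68 at 24 h (difference -5.18, SE 0.334, adjusted p = 3.2e-05). Os06g0142400, the locus that had risen by 5.13, was at 0.23 ± 1.85 at 24 h (difference -4.90, adjusted p = 0.0046), and was well above background in the treated channel on 1 of the 3 long arrays.

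Of all 23464 genes tested, 3834 were higher and 5238 lower at 24 h than after the short exposure. Among the 265 microRNA probes, 17 were higher and 20 were lower, of which 6 were at least 2-fold higher and none was 2-fold lower. The 6 included the miR528 5'seq, miR399i Mature, miR399b 3'seq, miR408 5'seq and miR160e 3'seq probes, with differences of 1.38, 2.71, 2.65, 1.70 and 1.52. For miR408 5'seq the mean log2 control signal was 10 on the short and 8.918 on the long arrays. Its treated signal was 9.75 and 10.37, so a lower control entered that difference. For miR399i Mature the control was 8.103 and 9.707 and the treated signal 8.263 and 12.58, so a higher control entered there. In the control channel test, the differences were 1.78 for miR399i Mature, 0.72 for miR399b 3'seq, 0.50 for miR160e 3'seq and -0.33 for miR528 5'seq. Their limma adjusted p were 0.056, 0.074, 0.054 and 0.19. The miR528 3'seq probe was the last of the 6, and its difference has no size, since neither channel was well above background on any short array. The miR171h 5'seq probe fell further (difference -0.95, SE 0.106, adjusted p = 0.00033, and -1.43 with Agilent's processed signals). For the miR171f 5'seq and 3'seq and the miR171g 3'seq probes the difference did not pass (adjusted p = 0.2 to 0.37). Neither did that of miR171f Mature (limma adjusted p = 0.12).

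Of the 1079 genes that were 2-fold higher after the short exposure, 854 were also higher at 24 h. By the test of the difference, 585 of the 1079 were lower at 24 h than before and 176 were higher still. Of the 1141 genes that were 2-fold higher at 24 h, 725 lay above their short ratio by the same test, and of the 803 that were 2-fold lower, 712 lay below it. Each set was chosen on a ratio that the test uses again, which favours a smaller change at the other exposure, so these counts describe the sets and give no overall direction. In both exposures 532 genes were at least 2-fold higher and 96 at least 2-fold lower, against 52.5 and 5.13 for independent lists. A further 10 genes were 2-fold higher after the short exposure and 2-fold lower at 24 h. The log2 ratios of the exposures correlated across genes with Pearson's r of 0.624 and Spearman's rho of 0.599. The covariance was 0.213. It is not stated whether arrays shared their control RNA. In simulated unchanged genes, with each short array sharing its control RNA with 1 long array and that RNA giving a share of 0.5 or 1 of the noise variance, r was 0.499 and 1, the covariance was 0.00353 and 0.00712, and 0 genes were called 2-fold in both. One control pool on all arrays would add its own deviation to every ratio, which the spread between arrays does not hold, so how much of the overlap and correlation would come from it is not known.

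**Figure D3:**
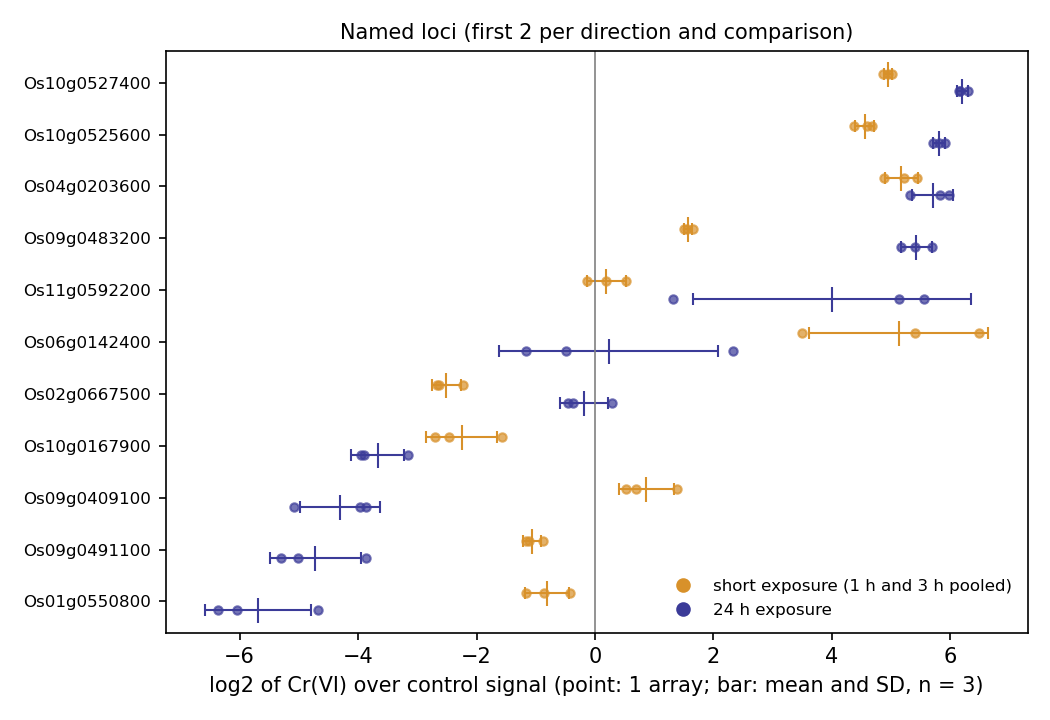
Log2 ratio of treated over control signal (horizontal axis) for the 11 loci named here, the first 2 in each direction and comparison under the naming rule; each point is 1 array, and bars give the mean and SD of 3 arrays per exposure. Os10g0527400 and Os10g0525600 rose at both exposures, while Os06g0142400 rose after the short exposure and lay between -1.16 and 2.33 at 24 h; the control signals of Os04g0203600 and Os09g0483200 were not well above background on any short array.

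In total 9072 genes differed between the exposures, 3834 higher and 5238 lower at 24 h. Median centring gave 1910 higher and 6290 lower, and 428 higher and 1261 lower at 2-fold. No slide held both exposures, so no value within a slide can be given. With the slide as a random block 10445 genes differed, where the estimated correlation of arrays on one slide was -0.106. A negative correlation narrows the error of a difference that lies between slides. The larger count therefore does not allow for slide effects.

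The control roots themselves, read in Cy3, were compared between the exposures because the difference of ratios includes them. Of 23464 genes, 823 differed, 668 higher and 155 lower in the controls of the 24 h arrays. Since the 24 h arrays all lay on slide 3 and the short arrays on slides 1 and 2, a difference of the roots cannot be told apart from one of the slides. In a single channel nothing on the array cancels a slide effect. Os02g0667500, which had fallen after the short exposure, was higher in those controls by 1.17 (SE 0.168, adjusted p = 0.021), Os10g0525600 was higher by 0.69 (SE 0.125, adjusted p = 0.034), and the miR408 5'seq probe was at -0.97 (SE 0.182, adjusted p = 0.036). Of the 1401 genes with a 2-fold difference of ratios, 16 had a 2-fold control difference of opposite sign that passed the control test. Control differences that did not pass are left out of the 16, so it does not measure how far the controls entered the 1401. The count of 823 rests on single arrays. It was 0 without short replicate 3 or without long replicate 1, and 5 without long replicate 2. It was 306 without long replicate 3, 330 without short replicate 2 and 4971 without short replicate 1. Without the short arrays on slide 2, the slide with the high green background, the split turned, with 56 higher and 78 lower. At an unadjusted p under 0.05 limma called 4606 and 3911 genes where the adjusted count was 0.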

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

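Of the tests in this part, the one of control RNA shared by replicate number and the one of centring were chosen after the results were seen.

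The ratio of treated over control differed between the exposures for 9072 genes, and by at least 2-fold for 1401. No slide held both exposures, so exposure and slide cannot be told apart here. The difference also includes any difference of the control roots. Among the loci given in the report, the 24 h minus short difference passed the test for Os06g0142400 (-4.90), Os02g0667500 (2.33), Os10g0167900 (-1.42), Os10g0527400 (1.26), Os10g0525600 (1.26), Os01g0550800 (-4.88), Os09g0491100 (-3.67), Os11g0592200 (3.81) and Os09g0409100 (-5.18), and also for Os09g0483200, whose fitted 3.86 is no measured size because its short ratio is only a bound. Of the 265 microRNA probes 17 passed higher and 20 lower. Among those that changed at least 2-fold in a comparison, it passed for miR399i Mature (2.71), miR399b 3'seq (2.65), miR528 5'seq (1.38), miR408 5'seq (1.70), miR408 Mature (0.879), miR160e 3'seq (1.52), miR531 5'seq (0.567), miR414 5'seq (0.225), miR171h 5'seq (-0.949) and miR171h 3'seq (-0.53). The miR528 3'seq probe passed too, but its fitted 3.25 is no measured size, since neither channel was well above background on any short array. With the arrays scaled after loess the differences of Os10g0527400 (0.32, adjusted p = 0.08) and Os10g0167900 (-0.93, adjusted p = 0.057) missed the threshold and that of Os10g0525600 was 0.39 (0.78 with Agilent's processed signals). The miR414 5'seq difference was lost without any 1 of the 6 arrays (adjusted p = 0.057 to 0.13), and the miR531 5'seq difference with median centring (adjusted p = 0.061). With Agilent's processed signals miR408 Mature was at 1.45 and miR171h 3'seq at -1.41. The control channel of miR408 Mature was well above background on 1 of the 3 short arrays. The treated channel of miR171h 3'seq was so on 2 of the 3 short and 1 of the 3 long arrays.

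Of 59 probes built into the design as controls, which entered no comparison, 15 were well above background on at least 3 arrays; of these 6 were higher in the treated channel at an exposure, 1 was lower and 8 passed at neither. One genome probe had a log2 ratio of 1.66 at both exposures, another 0.90 after the short exposure and 1.02 at 24 h, and one more 0.322 after the short exposure and -0.012 at 24 h. A wheat-named probe had 0.319 and 0.265, and random-sequence probes had 0.341 and 0.438, 0.0146 and 0.234, and, for the one that was lower, -0.225 and -0.183, each pair in the same order. None of the 12 artificial-sequence probes was well above background on 3 or more arrays.

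For the short exposure the real signs of the 3 arrays gave 12837 genes, and the highest of the other 3 sign patterns gave 1; for 24 h they gave 15151 and 1. For the difference of exposures the real split gave 9072 genes and the highest of the other 9 splits gave 0, and for the control roots 823 and 0. In each case 1 pattern, the real one, was as large, and with 4 sign patterns or 10 splits no share under 0.05 can be had.

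Genes called in the same direction at both exposures could in principle reflect a bias of the probe for Cy5, since no dye was swapped. A second probe of the same locus, at least 2-fold dimmer, had the sign of the called probe for 87.1% of 800 loci (95% exact interval 84.6% to 89.4%). That argues against a bias of single probes as the whole cause, though the positions of the probes were not known. Some design controls were also called in the same direction at both exposures. Random-sequence probes were at 0.341 and 0.438 and at -0.225 and -0.183, and a wheat-named probe was at 0.319 and 0.265. One genome probe was at 1.66 at both exposures, and another was at 0.90 after the short exposure and 1.02 at 24 h. Of the 15 design controls well above background on at least 3 arrays, 8 passed at neither exposure. Ratios of one direction at both exposures, small ones and some beyond 2-fold, can thus arise on probes without a named rice locus. Control RNA shared by arrays with one replicate number would make their deviations correlate positively, and the mean correlation was -0.15. That gives no sign of such sharing, but 3 arrays per exposure cannot exclude it. One control pool for all arrays, a bias shared by both probes and a lasting response of the roots to Cr(VI) stay open, the last as a hypothesis.

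Genes that changed at least 2-fold after the short exposure mostly rose, in 87.8% of cases. A dim control channel is argued against for genes bright in both channels on all 6 arrays, where 86.5% rose, and the high green background of slide 2 is argued against by the single arrays, of which the lowest, on slide 1, had 83.2%. With Agilent's processed signals, which differ in background handling, dye normalization and offset at once, the share was 71.6% of 2584 genes. It was 88.6% with median centring, 88.2% without background correction and 86.2% with a normexp offset of 16. Processing may thus account for part of the excess, although most genes still rose under each setting. Which step of Agilent's processing lowered the share cannot be told from these values. An early response made up mainly of induction stays open as a hypothesis.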

How the results depend on the processing

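Chosen after the data were seen was only the omission of the short arrays on slide 2. Agilent's processed signals, which have no offset, gave 2584, 3598 and 2479 genes at 2-fold for short, 24 h and their difference, against 1229, 1944 and 1401, and shared 1206, 1907 and 1296 of those calls in the same direction; the series table, made from the same signals, gave 2620, 3671 and 2504. Without the short arrays on slide 2, which leaves 1 short array assumed to vary like the others, 6377 genes passed for short, 4599 for the difference and 134 for the control roots, against 12837, 9072 and 823; fewer arrays entered. Scaling the control channel to the same median gave 1897 genes for the control roots, and leaving out 1 array gave 0 to 4971; the cause was not tested. All other totals of genes, both directions together, stayed within 1.5 times. By direction, median centring moved more than that for the 7895 higher (5171) and the 803 2-fold lower (1321) at 24 h and the 3834 higher in the difference (1910), and demanding both channels above background took the 515 2-fold higher in the difference to 330. Agilent's processed signals gave 1865 higher and 1733 lower at 24 h and 941 and 1538 for the difference, all at 2-fold. With the replicate number as a block, 11392, 14061 and 7482 genes passed and 1232, 1944 and 1405 at 2-fold. The deviations of same-numbered arrays correlated at -0.234, -0.116 and -0.1 and no array matched its own number best. That gives no sign of a pairing by number, but 3 arrays per exposure cannot exclude one. The correlation of the exposures stayed between 0.603 and 0.639. For 71 values of named loci and microRNA probes that passed, 1487 of 1527 recomputed values kept direction and call, 39 lost the call, 10 of them without the short arrays on slide 2, and 1 turned, the miR414 5'seq difference, which was -0.0129 with median centring. The differences of Os11g0592200 (adjusted p = 0.13) and Os06g0142400 (-3.27, adjusted p = 0.088) were among those lost without slide 2. Sizes moved by over 1.5 times in 39 of the 1527. The miR395 median at 24 h was 0.0735 and turned to -0.0679 with median centring, which also took the 10 rising miR156 probes at 24 h to 6; demanding both channels above background left 6 of 14 tested. The gene list alternatives were not run, since no list could be filled. The offset and the green background of slide 2 limit dim genes on those short arrays, where negative control spots read 194 in green against 78 to 89.5 on the others.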

Other observations

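The pattern of neighbouring loci was noticed in the data before its explanations were tested, and the comparisons of chromosomes and of the 5'seq and 3'seq probes were chosen after the data were seen.

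Loci with neighbouring numbers changed together. The longest run of rising loci at 24 h held 6 consecutive tested loci on chromosome 7, with log2 ratios from 1.16 to 2.78 and a median of 0.09 after the short exposure; 1 other run was as long. The longest runs of falling loci held 4, one of them on chromosome 4 with ratios from -1.84 to -1.55. In all there were 16 runs of at least 3 rising loci and 10 of at least 3 falling loci. Loci that rose 2-fold at 24 h made up 6.07% of the tested loci of chromosome 1, against 4.88% of all tested loci (Fisher's exact test, two-sided, odds ratio 1.32, adjusted p = 0.0376 over 48 tests, with loci not independent).

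Of 23176 pairs of neighbouring tested loci, 209 changed at least 2-fold in the same direction at 24 h, against a mean of 82.4 and a highest value of 112 in 1000 shuffles of the calls (permutation p = 0.001, the smallest they can give). Spots lying close together on the array are argued against as the whole cause, because 162 such pairs had spots over 50 rows apart, against at most 93 in the shuffles. If they read one transcript, co-changed neighbours could differ as little as 2 probes of one locus. The median difference was 0.481 for co-changed neighbours (95% bootstrap interval 0.403 to 0.62) and 0.1 for 2 probes of one locus. That 0.1 covers only second probes that also changed at least 2-fold in the called direction. Where loci were 2-fold at both exposures, second probes at least 2-fold dimmer gave a median of 0.767 of the first probe's ratio. Probes of one locus can thus differ by more, so the comparison does not decide the question for every pair. Partial cross-hybridization between tandem copies was not tested, since no probe sequences were used here. Clusters of related genes that respond together may account for the rest, as a hypothesis.

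Over 70 pairs of a 5'seq and a 3'seq probe of one microRNA locus, the log2 ratios correlated across loci with Pearson's r of 0.529 and Spearman's rho of 0.505 after the short exposure and 0.634 and 0.597 at 24 h. At either exposure 47 of the 70 pairs had the same sign.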
